A study of Mus musculus with 8 samples.

How the data were processed

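RNA sequencing was carried out on mesenchymal progenitors sorted by flow cytometry from whole hindlimb muscle of C57BL/6J mice. Mesenchymal progenitors are stromal cells of the muscle interstitium. They carried a tamoxifen-inducible Cre at the Hic1 locus and a tdTomato reporter behind a floxed stop at Rosa26, so the red fluorescence marks cells, and descendants of cells, that expressed Hic1 when tamoxifen was given. Per the labels' protocols, the mice were 8 weeks old at tamoxifen treatment (2.5 mg daily for 5 days, then a washout), polyA RNA was used and the library kit kept the strand. The 8 libraries were 1 from quiescent progenitors and 1 each from days 1, 2, 3, 4, 5, 7 and 10 after injury with notexin, a snake venom phospholipase that destroys muscle fibres. Each time point is 1 library, and whether RNA of several mice was pooled for it is not stated. The time point of each library was taken from its label.

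The authors deposited 1 table of FPKM values (fragments normalised to transcript length and to the total of mapped fragments) for 23846 rows, each with a gene symbol and a locus. Per the submitters' processing notes, bcl2fastq, TopHat2, Bowtie2 and Cufflinks were used with the mm10 build, with no versions or roles given. The gene annotation, the filters, the use of strand and the treatment of reads that map to several places are not given in the sources used here. FPKM depends on the transcript models and on the total of mapped fragments, so a shift of a few abundant genes moves the values of all others. Values of 0.001 fill between 6827 and 8217 rows per library, and 312 or 313 rows per library are listed at exactly 0. A value at 0 or 0.001 was read as a floor, and no fold of a single gene was taken against it in the text. List medians keep members at the floor. A total of 253 symbols stand on more than 1 row (749 rows). These rows were kept apart. The deposited locus starts were raised by 1 to give coordinates counted from 1 on mm10, the assembly also known as GRCm38.

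No total counts stand in the table, so depth was estimated from its low values. In 2088 genes with a single transcript longer than 1500 bp in GENCODE M21, FPKM times transcript length less 150 bp falls in steps of what 1 fragment is worth. The step gave 18.9 M (mega) fragments for the quiescent library, 14.3 for day 1, 10.7 for days 2 and 3, 12.2 for day 4, 14.0 for day 5, 12.7 for day 7 and 28.6 for day 10. Between 72.5% and 77.7% of the values worth 1 to 5 fragments lay within 0.15 of a whole number, where 30% would by chance. At these depths a gene of 2 kb at 5 FPKM rests on 107 to 286 fragments, which gives a counting error of 0.09 to 0.14 on the log2 scale. This covers counting only. Differences between animals, sorts and library preparations are not measured by it and add to it.

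Differences were taken on log2(FPKM + 1), so the change of genes with low FPKM is understated. A gene counted as higher or lower when this differed by 1 or more (2-fold, on that scale) and its FPKM was at least 5 in the higher library. A difference of 2 or more was counted as 4-fold. With 1 library per time point no test across genes was made and no p-value is given for a gene. Peak days were counted among genes whose log2(FPKM + 1) spanned 2 or more over the libraries and whose highest FPKM was at least 5. The order of the libraries in time was tested with an exact permutation test over all 20160 orders of the 8 libraries, reading an order forwards or backwards being the same, on the summed distance (1 minus the Spearman correlation across 9509 genes at 5 FPKM or more in any library).

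Before the data were examined, 30 gene lists and 8 lists of markers of other cell types were fixed. A member was measured when it reached 1 FPKM in any library. For each list the median difference from quiescent was ranked among those of 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins, as a description of these libraries. A median in the text lies outside the middle 95% of the random lists unless it is said to lie inside. The lists overlap in part. The genes named by rule were the 12 with the largest increase and the 12 with the largest decrease at days 1, 3, 7 and 10, with at least 10 FPKM in the higher library and a change of at least 0.5 in the same direction at a neighbouring injured time point. The rule also took up to 4 members of each list (2 up and 2 down at the day where the list's median was farthest from 0) and a fixed set (Hic1, Pdgfra, Ly6a, Mki67, Ccl2, Col1a1, Acta2, Pax7, Ptprc, Pecam1 and the sex-linked genes). Rows spanning under 200 bp, mostly small nucleolar RNAs and microRNA precursors, took between 4 and 12 of the 12 places in each of these sets, so the same rule was also run on rows of 200 bp or more. That change was chosen after seeing the data, and other members of the fixed lists named in the text were also picked after their values were seen. One gene that the rule names is not reported here.

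The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a minimum of 20 FPKM, rescaling each library to a common sum, scaling by the median ratio to the geometric mean over genes above 5 FPKM in all 8 libraries, the median over the 8 libraries as the reference, the mean over list members, Euclidean distance, each library left out of the order test, and rows of a repeated symbol summed. Alternatives added after seeing the data left out rows under 200 bp, left out the day 3 or the day 5 library, or removed the median difference of 10 bins of transcript length and 10 bins of GC content. Length and GC came from GENCODE M21 transcripts and were found for 94.6% of the 9509 genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

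The steps were tested on simulated data. For a day against quiescent at 10 M fragments with counting error only, run on 23846 rows, 50 of 50 genes changed 3-fold, 50 of 50 changed 4-fold, 50 of 50 changed 8-fold and 0 of 50 changed 1.5-fold were called, and 7 of 23646 unchanged genes were. Of 200 unchanged random lists, 193 lay in the middle 95%. The depth step returned 9.97 M fragments for 10 M simulated.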

Results

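RNA sequencing measured transcript abundance (FPKM) in purified Hic1-lineage mesenchymal progenitors of mouse hindlimb muscle, the stromal cells that lie between muscle fibres. 1 library was made from quiescent tissue and 1 at each of days 1, 2, 3, 4, 5, 7 and 10 after notexin injury. With 1 library per time point no difference could be set against the spread between animals, and what follows describes these 8 libraries. The estimated depth ran from 10.7 M fragments at day 3 to 28.6 M at day 10. Coordinates are on mm10.

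The comparison of each injured library with the quiescent one asked how large the response of these cells was and how long it lasted. Chemokine, cell division and ribosome assembly genes were prominent early, and collagens and genes of tendon were among those high later. At day 1, 1954 genes were at least 2-fold higher and 1091 at least 2-fold lower than in quiescent, and the counts were 2099 and 962 at day 2 and 1376 and 724 at day 3. They were 381 and 180 at day 4, 710 and 389 at day 5, 336 and 205 at day 7, and 260 and 102 at day 10. As a share of the genes compared, this was 35% at day 1, 34.6% at day 2, 24.0% at day 3, 6.72% at day 4, 13.0% at day 5, 6.46% at day 7 and 4.30% at day 10. Changes of 4-fold or more were made by 753, 782, 526, 133, 195, 109 and 110 genes at the 7 days in order.

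Which direction held more genes depended on the scaling. FPKM summed to 463650 in the quiescent library, 673684 at day 1 and 718618 at day 2, and the fifth of genes with the shortest transcripts had a median log2 difference of 0.44 at day 1, against -0.08 for the fifth with the longest. The median over all genes lay 0.22, 0.25, 0.20, 0.05, 0.08, 0.07 and 0.07 above quiescent on the log2 scale at the 7 days in order. Scaling by the median ratio moved it by -0.30, -0.33, -0.22, -0.08, -0.12, -0.08 and -0.06, and rescaling to a common sum by -0.48, -0.58, -0.40, -0.14, -0.35, -0.22 and -0.02. Under median-ratio scaling, more genes were lower than higher at day 1 (1248 higher, 1694 lower), day 2 (1254 and 1562) and day 3 (948 and 1059). The split was 339 to 249 at day 4 and 558 to 557 at day 5. Rescaled to a common sum, it was 1080 to 2770 at day 1, 1015 to 2807 at day 2, 907 to 1828 at day 3, 433 to 434 at day 4, 482 to 1313 at day 5 and 326 to 571 at day 7. The direction of the counts is therefore not given at days 1 to 5 and day 7. Rescaling also lowered the medians of most gene lists given below at days 1 to 3, so rises were smaller and falls larger than on FPKM as deposited.

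**Figure D1:**
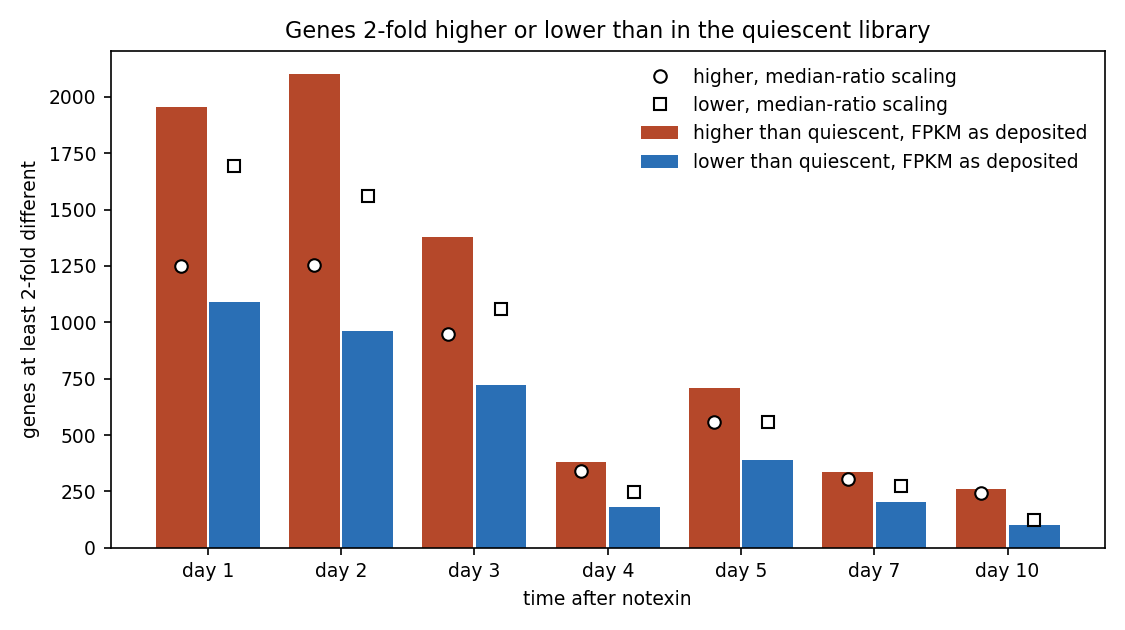
Number of genes at least 2-fold higher or lower than in quiescent at each day after notexin (1 library per time point), with bars for FPKM as deposited and markers for median-ratio scaling. The count is largest at days 1 and 2 and is higher at day 5 than at day 4.

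Between neighbouring time points, 3045 genes differed 2-fold from quiescent to day 1. The later steps held 735, 683, 704, 184, 224 and 112 genes. Of 1673 genes that spanned 4-fold or more, 415 had their highest FPKM at day 1, 360 at day 2, 211 at day 3, 52 at day 4, 104 at day 5, 116 at day 7, 167 at day 10 and 248 in quiescent. The number peaking at day 1 was 271 under median-ratio scaling.

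Return at day 10 was common among genes of the early response and rarer among those of the late one. Of 3077 genes higher at any of days 1 to 7, 2765 (89.9%) were within 2-fold of quiescent at day 10, as were 1355 of 1482 lower genes (91.4%). Among all 8422 genes compared at day 10, only 4.30% were 2-fold from quiescent, so these shares do not set the genes apart as returning more than others. Of the genes higher at day 1, 93.3% were within 2-fold at day 10, and of those higher at day 7, 46.7%. A further 53 genes were higher and 9 lower for the first time at day 10.

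The order of the libraries was tested to see whether neighbours in time were close. Along the time course the summed distance was 0.625, and 387 of 20160 orders were as short (exact permutation test over the 8 libraries, one-sided, p = 0.0192). Without 1 library at a time p ran from 0.000794 (without quiescent) to 0.154 (without day 2). It was above 0.05 without day 1 (0.140), day 2, day 3 (0.0996) or day 7 (0.0647), so the call rests on these libraries. The shortest order was quiescent, day 10, 7, 4, 5, 3, 2 and 1, with a distance of 0.433. Across genes, which are not independent replicates, the Spearman correlation with quiescent was 0.762 at day 1, 0.753 at day 2, 0.801 at day 3, 0.917 at day 4, 0.886 at day 5, 0.924 at day 7 and 0.942 at day 10. Day 3 correlated more with day 5 (0.931) than with day 2 (0.921).

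**Figure D2:**
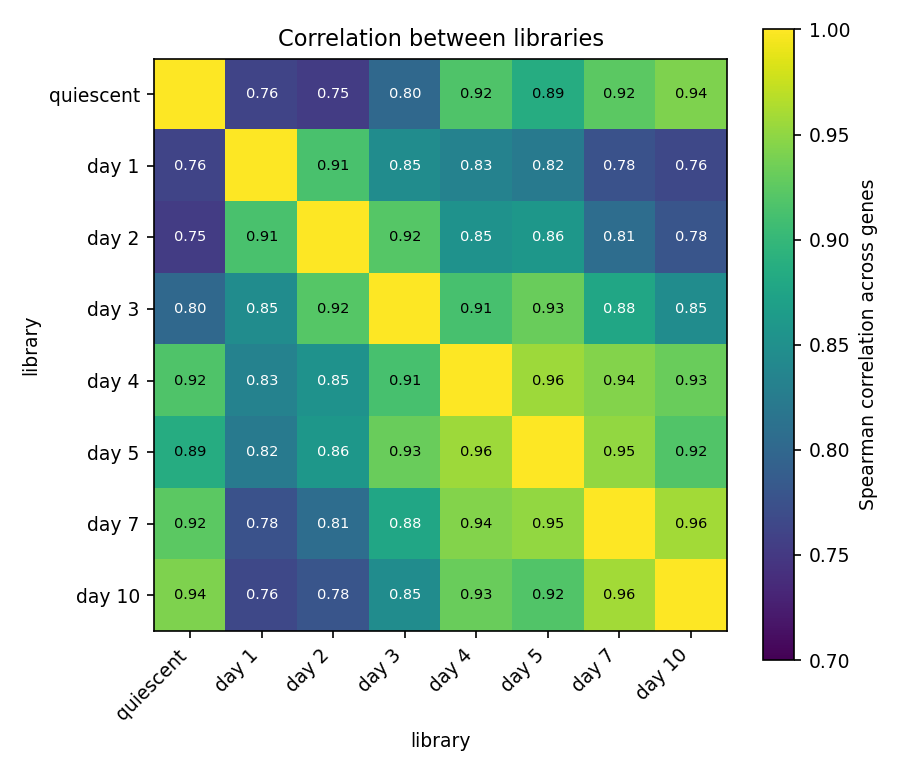
Spearman correlation across genes between each pair of the 8 libraries, colour scale from 0.70 to 1.00. Days 1 and 2 lie farthest from quiescent (0.76 and 0.75), and day 10 lies nearest to it (0.94).

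The comparison of day 1 with quiescent asked what the cells turned on first. Among genes spanning 200 bp or more, chemokines that draw neutrophils, an interleukin 33 receptor and an acute phase protein were among the largest increases. The matrix protease inhibitor Timp1 and enzymes of serine synthesis rose with them. Cxcl5 (chromosome 5, 90759299 to 90761625) rose from 0.035 FPKM to 1269.0. Ccl2 rose from 133 to 2780.1 and Cxcl1 from 416 to 3840.3. Timp1 (chromosome X, 20870166 to 20874737) rose from 15.9 to 1581.2, and Il1rl1 from 0.61 to 202. Saa3, listed at the floor in quiescent, reached 113. Of 29 measured chemokine and cytokine genes 17 were higher, with a median log2 difference of 1.76, and macrophage and monocyte markers were higher at the same time (median 1.15 at day 1 and 1.35 at day 2). The NF-kB and acute phase list had a median of 1.1 (9 of 20 higher, 0.62 when rescaled to a common sum), and heat shock proteins 1.3 (0.78 when rescaled), led by the mitochondrial chaperones Hspe1 (72.6 to 578) and Hspd1. In the same list Hspa1a (845 to 314) and Hspa1b, near-identical copies whose values are uncertain, were lower.

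Growth genes moved at the same time. All 30 ribosome biogenesis genes, whose products build ribosomes in the nucleolus, were higher, with a median of 2.28, and Ncl rose from 25.2 to 237. The S phase list had a median of 2.54 (24 of 30 higher) before the G2 and M list had moved as far (1.04, 7 of 30). Mcm5, part of the replication helicase, rose from 1.04 to 48.6. Glycolysis and hypoxia genes had a median of 0.73 (0.29 when rescaled to a common sum), with Ldha at 89.5 in quiescent and 597 at day 1. Ribosomal proteins of the cytosol had medians of 1.14 at day 1 and 1.23 at day 2 (0.60 at each when rescaled). Both medians as deposited lay inside the middle 95% of random lists.

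What fell at day 1 included genes of the resting state and of the vessel wall, and markers of endothelial cells, Schwann cells and muscle fibres fell with them. The Wnt modulator Dact2, the methyltransferase Inmt, the olfactomedin Myoc and the pericyte gene Rgs5 were among the largest decreases. Dact2 fell from 150.1 FPKM to 4.78, Inmt from 258 to 10.1, Myoc from 1813.2 to 109 and Rgs5 from 35.3 to 0.98. Wnt10b fell from 42.1 to 2.06 and the integrin Itga11 from 56.8 to 3.61. The pericyte and mural list had a median of -2.25 (16 of 19 lower), basement membrane genes -1.04, the Wnt and Hedgehog list -1.13 and limb Hox genes -0.69. Matrix glycoproteins and proteoglycans had a median of -0.85, with Fmod at 55.7 in quiescent and 6.07 at day 1. Markers of resting fibroblast subsets had a median of -1.89 at day 1 and -1.97 at day 2, when Pi16 stood at 227 against 2361.9 in quiescent. The progenitor identity list had a median of -1.12 at day 1, where Gsn and Col6a1 were lower and Vim was higher. Hic1 (chromosome 11, 75164565 to 75170255) fell from 52.2 in quiescent to 20.6 at day 1. Pdgfra (118 and 153) and Ly6a (953 and 1682.3) stayed within 2-fold.

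Days 2 and 3 were compared with quiescent to follow division and the cells' metabolism. Mitotic genes peaked at day 2, together with those of cholesterol synthesis, mitochondrial respiration and the secretory pathway. The survivin gene Birc5 (chromosome 11, 117849237 to 117855743) rose from 1.42 to 140.45 at day 2 and stood at 80.8 at day 3. Mki67, a marker of cycling cells, went from 0.45 to 26.1. The G2 and M list had a median of 4.09 at day 2 (28 of 30 higher) and 3.29 at day 3, and it was still 1.26 at day 10 (7 of 30). The S phase median was 2.62 at day 2 and 1.69 at day 3. Cell cycle inhibitors and p53 targets had a median of -0.28 at day 1, inside the range of random lists, with members moving both ways, and Cdkn1a fell from 119.9 in quiescent to 20.9 at day 3.

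Cholesterol synthesis had a median of 1.55 at day 2, with Fdps at 285 against 29.3. Oxidative phosphorylation had a median of 1.35 (0.73 when rescaled to a common sum) and the secretory and unfolded protein list 1.45 (0.83), with Sec61b at 755 against 116. Myogenic support and growth factors had a median of -0.70 at day 2. Igfbp5 fell from 1016.1 to 96.3 there, and the lipoprotein lipase inhibitor Angptl4 rose from 16 to 98.1. Matrix proteases and inhibitors moved both ways at day 2 (6 higher and 7 lower, median -0.46, mean -0.0043), where Timp2 and Timp3 fell and the protease Adam12 rose from 0.35 to 27.6. Complement genes had a median of -1.41 at day 2, and C7 reached 3.27 at day 3 against 112 in quiescent.

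At day 3 interferon-induced genes and transcripts of macrophages were high. The interferon list had a median of 1.70 (23 of 30 higher), with Isg15 rising from 13.7 to 257. The osteopontin gene Spp1 rose from 1.34 to 206. The lysosomal genes Lyz2 (8.89 to 391) and Ctss (1.47 to 122) and the receptor adaptor Tyrobp (2.20 to 93.7) rose too. These 3 belong to the macrophage marker list, whose median was 2.96 at day 3, 1.23 at day 4 and 2.65 at day 5, so part of this change lies in markers of another cell type. The haptoglobin gene Hp rose from 0.49 to 74.5. Hp (74.5, 6.46 and 35.6 at days 3, 4 and 5) and Spp1 (206, 30.5 and 49.9) were also lower at day 4 than at days 3 and 5. Which cells these transcripts came from was not tested. Adipogenic genes had a median of 0.30 at day 3, within the range of random lists. In that list Apoe stood at 162 in quiescent and at 536, 170 and 535 at days 3, 4 and 5. It too was lower at day 4 than at days 3 and 5, as the macrophage markers were.

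**Figure D3:**
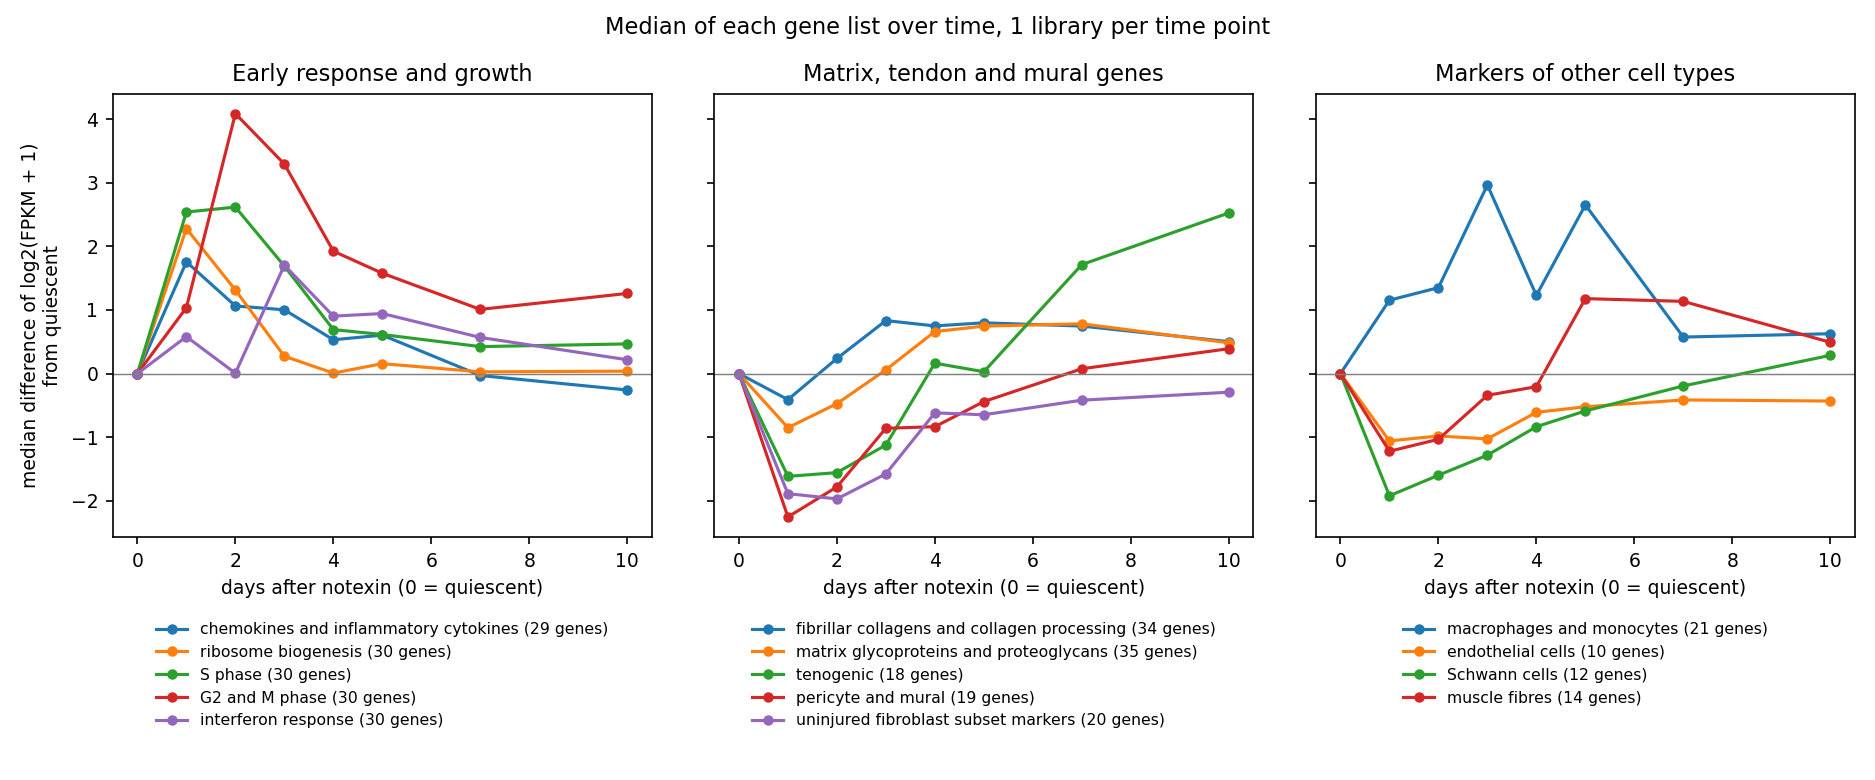
Median log2 difference from quiescent of gene lists at each day after notexin, in 3 panels, FPKM as deposited. The G2 and M list reaches 4.09 at day 2 and the tenogenic list 2.52 at day 10.

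Days 4 to 7 were compared with quiescent to follow matrix production. Collagens and their processing enzymes, matricellular proteins of healing tissue and Cthrc1, a secreted protein of activated fibroblasts, were high. Postn (chromosome 3, 54361107 to 54391041) rose from 56.2 FPKM to 1653.2 at day 4 and 2008.8 at day 5, and Cthrc1 from 2.34 to 256 at day 5. Col1a1 stood at 1174.1 in quiescent, 4894.3 at day 4 and 4612.2 at day 7. The collagen list had medians of 0.83 at day 3, 0.75 at day 4, 0.80 at day 5 and 0.75 at day 7, and when rescaled 0.40, 0.68, 0.46 and 0.52. The matrix glycoprotein list had 0.66 at day 4, 0.75 at day 5 and 0.78 at day 7, and when rescaled 0.52, 0.37 and 0.55. Its median at day 3, 0.06, flipped to -0.19 under median-ratio scaling and -0.37 when rescaled to a common sum. Myofibroblast and contractile genes had a median of 0.75 at day 3 (0.33 when rescaled) and 0.65 at day 10, and Acta2 rose from 22.5 in quiescent to 83.1 at day 3.

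The collagenase Mmp13 rose from 0.29 to 37.4 at day 5 and 30.2 at day 7. The imprinted genes Mest (8.11 to 141 at day 7) and H19 (21.9 to 269 at day 7) rose as well, both being highest at day 5, when markers of muscle fibres were higher too. By day 7 the tendon transcription factor gene Scx had risen from 3.72 to 69.6 and the junctional collagen gene Col22a1 from 2.95 to 45.2. The largest decreases at day 7 among genes spanning 200 bp or more included Has1, Ptgs2 and Nr4a1. The hyaluronan synthase Has1 fell from 294 to 63.2, the prostaglandin synthase Ptgs2 from 79.5 to 20.5 and Nr4a1 from 316 to 84.3. The globin gene Hbb-b2 was lower at day 7 (52.7 to 13.8) and stood at 88.3 at day 5.

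The comparison of day 10 with quiescent asked what was left when most genes were back. Genes of tendon cells were prominent among the largest increases, Tnmd encoding a membrane protein of mature tendon. Some inflammatory genes were below their level in the quiescent library, and whether that level was a resting one was not tested. Scx (chromosome 15, 76457438 to 76459468) rose from 3.72 to 95.4, Tnmd (chromosome X, 133851008 to 133865578) from 23.9 to 437, Col22a1 from 2.95 to 98.0 and Kera from 8.56 to 154. Thbs4 rose from 89.8 to 1291.0. The tenogenic list had a median of -1.62 at day 1, 1.71 at day 7 and 2.52 at day 10 (11 of 18 higher). The pericyte and mural list had a median of 0.39 at day 10, with Rgs5 at 74.0. The osteogenic and chondrogenic list had 0.94, with only 11 of 20 genes measured. This median is the difference of Chad itself (12.8 against 6.19). Of the 11 genes 6 lay above quiescent, and 2 were 2-fold higher.

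The chemokine and cytokine list had a median of -0.26 at day 10 (8 of 29 lower, 1 higher) and the NF-kB list -0.31 (5 of 20 lower), and the interferon list 0.22. Ptx3 fell from 106 FPKM to 17.5, Ccl2 from 133 to 32.8, Cxcl1 from 416 to 98.9, Nfkbia from 341 to 70.3 and Has1 from 294 to 33.7. Immediate early genes, which respond within minutes to stress, had medians of -0.32, -1.11, -1.10, -0.59, -0.66, -0.89 and -0.95 at the 7 days in order. Myc was 78.1 in quiescent and 21.9 at day 10. The heat shock median was -0.30 at day 10.

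**Figure D4:**
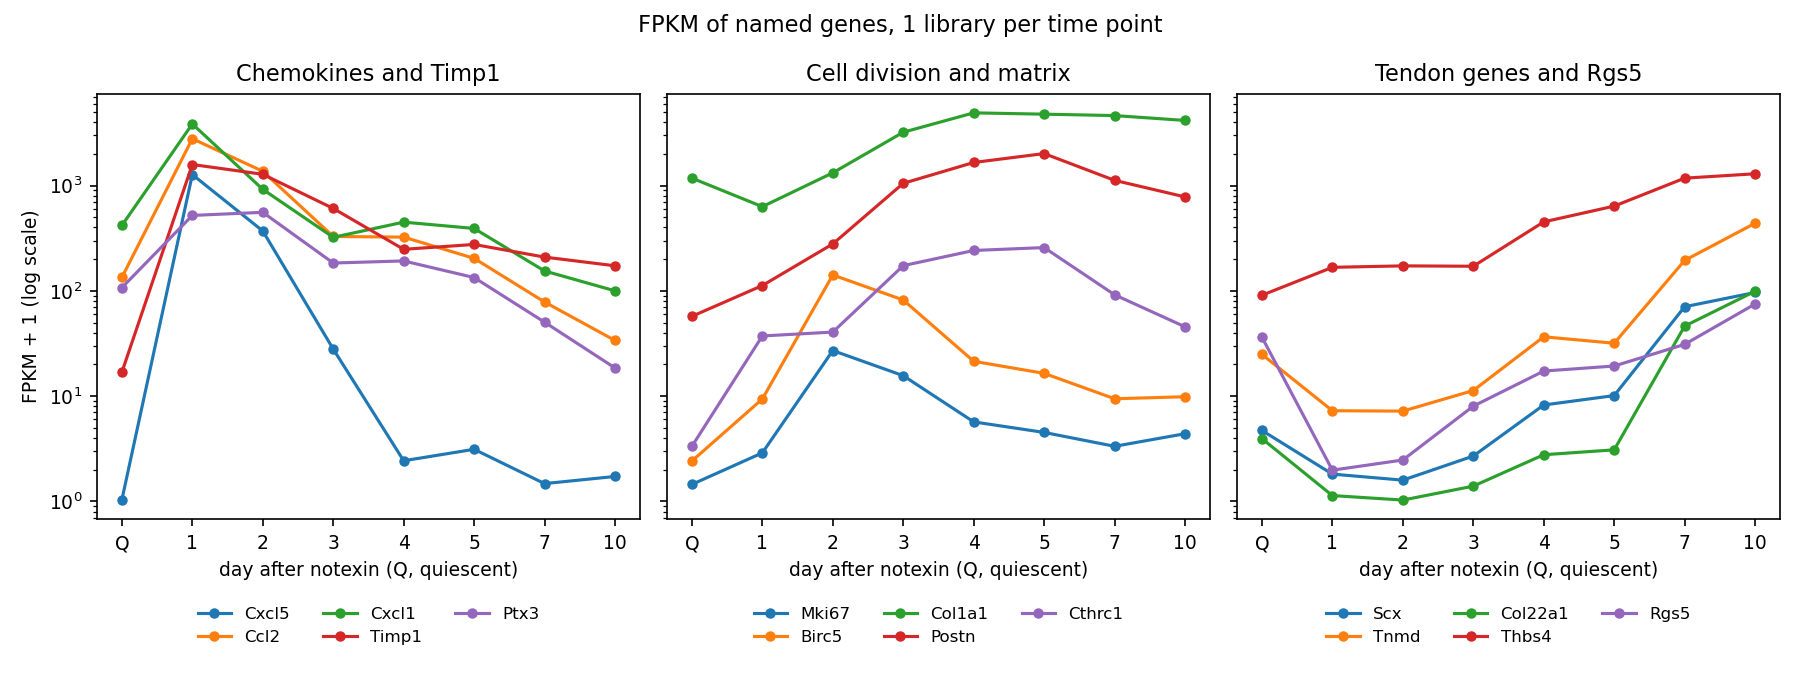
FPKM plus 1 (log scale) of 15 named genes in the 8 libraries, in 3 panels, Q being quiescent. Cxcl5 peaks at day 1, Birc5 at day 2, Postn at day 5 and Tnmd at day 10.

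Markers of other cell types were measured in the same libraries, since a sort can carry other cells over. Muscle fibre genes had a median of -1.22 at day 1, 1.18 at day 5 and 1.13 at day 7. At day 10 muscle fibre genes had 0.49, macrophage markers 0.63 and satellite cell genes 0.43. Endothelial genes had -0.43 and red cell genes -0.75 at that day. Schwann cell genes had a median of -1.92 at day 1. Endothelial genes had -1.06 at day 1. The largest fall among them was that of Tek (68.9 to 7.34), which also stands in the list of resting fibroblast subsets. Pecam1 was at most 1.93. Neutrophil genes had -1.66 at day 4 and 1.1 at day 5, with S100a8 at 0.43 at day 4 and 33.2 at day 5. Red cell genes had -1.38 at day 2, with 5 of 9 measured, and satellite cell and myoblast genes 1.18 at day 3, with 9 of 14 measured and Pax7 at most 0.18. Lymphocyte genes had 1.33 at day 5, with 2 of 14 measured. The medians of satellite cell, lymphocyte, (at day 2) red cell and (at day 4) neutrophil genes rest on a gene at the floor in 1 library compared. Their size is therefore uncertain. The leukocyte gene Ptprc was at most 2.31. The sex-linked genes had a largest median difference of -0.38, at day 2, inside the range of random lists, and the Y-linked Eif2s3y lay between 25.8 and 39.4 in all 8 libraries with Xist at most 0.029.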

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

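The removal of short genes, the correction for length and GC content and the settings without the day 3 or day 5 library were chosen only after the results were seen. No list median at its day farthest from 0 changed sign in the alternatives run. The matrix glycoprotein median at day 3 did, from 0.06 to -0.19 under median-ratio scaling and -0.37 when rescaled to a common sum, and the balance of higher and lower genes reversed at days 1 to 3 under both scalings. A count was taken to have moved when it differed by over 1.5 times, and a return share when it left its 95% Wilson interval. A list median had moved when the difference exceeded the distance from the middle to the edge of the 95% range of random lists. By these bounds 374 values of counts, list medians, return shares and order p-values stayed, 126 moved and 4 order tests lost the 0.05 threshold. Of the named genes' differences, 351 stayed within 1.5 times and 79 moved, all with a pseudocount of 0.1. Counting noise at 10.7 to 28.6 M fragments limits genes of a few FPKM, and variation between animals was not measured. No paired analysis was possible because each time point is 1 library.

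Rescaled to a common sum, 1080 genes were higher and 2770 lower at day 1, 1015 and 2807 at day 2, and 907 and 1828 at day 3. The lower counts were 434 at day 4, 1313 at day 5 and 571 at day 7, and 394 were higher at day 10. The steps from day 4 to 5 and day 7 to 10 held 308 and 240 genes. The return shares were 79.3% of higher and 94.4% of lower genes. This scaling divides by sums of FPKM that differ between libraries, and with the pseudocount of 1 genes of low FPKM move by other amounts. It moved the list medians to -2.61 for uninjured fibroblast subset markers, 2.22 for S phase, 1.39 for interferon response, -1.74 for immediate early genes, 0.73 for oxidative phosphorylation, 1.80 for ribosome biogenesis, 0.60 for cytosolic ribosomal proteins and 0.83 for the secretory pathway. It gave 0.40 for fibrillar collagens, -1.69 for basement membrane, -1.39 for matrix glycoproteins, -1.09 for matrix proteases, 0.33 for myofibroblast genes, -2.86 for pericyte and mural genes, -2.05 for complement, -1.31 for growth factors, -1.73 for Wnt and Hedgehog, 1.06 for cholesterol synthesis and -1.23 for limb Hox genes. Among marker lists it gave -2.45 for neutrophils, -1.65 for endothelial cells, -1.87 for muscle fibres and -2.75 for Schwann cells. The hypoxia and glycolysis list gave 0.29, the NF-kB and acute phase response list 0.62 and heat shock proteins 0.78. Each is at the list's day farthest from 0.

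Median-ratio scaling gave 1248 higher and 1694 lower genes at day 1, 1254 and 1562 at day 2, return shares of 86.1% and 93.1%, and 271 genes peaking at day 1. Size factors ran from 0.888 in quiescent to 1.15 at day 2.

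With the median of the 8 libraries as the reference, which holds the injured libraries too, 1117 genes were higher and 700 lower at day 1, 962 and 411 at day 2, 374 and 169 at day 3, 35 and 23 at day 4, 107 and 13 at day 5, and 104 and 62 at day 7, with 171 higher at day 10. The 4-fold counts were 311, 258, 73, 28, 30 and 37 at days 1, 2, 3, 4, 5 and 7. List medians became -1.29 for fibroblast subset markers, 1.91 for S phase, 2.57 for G2 and M, 0.93 for interferon, -0.25 for immediate early genes, 0.19 for hypoxia and glycolysis, 0.84 for oxidative phosphorylation, 0.74 for ribosomal proteins and 0.88 for the secretory pathway. They were 0.15 for collagens, -1.33 for matrix glycoproteins, 0.13 for myofibroblast genes, 1.77 for tenogenic, -1.66 for mural and 0.12 for osteogenic genes. Marker lists gave 1.84 for macrophages, -0.70 for neutrophils, -1.09 for Schwann cells and -0.055 for red cells.

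At a minimum of 20 FPKM, which tests fewer genes, the lower counts were 511, 480, 380, 95, 198 and 117 at days 1, 2, 3, 4, 5 and 7. The higher counts were 855, 213, 457, 182 and 121 at days 3, 4, 5, 7 and 10. The 4-fold counts were 509, 290, 72, 112, 67 and 67 from day 2 on. The steps between neighbours held 1904, 382, 408, 344, 95 and 125 genes up to day 7, and 87.6% of lower genes returned. With no filter, 581 genes were higher at day 4 and 409 at day 10, and 281 and 384 differed between days 4 and 5 and days 5 and 7, since genes of low FPKM enter.

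A pseudocount of 0.1 widens differences of genes with low FPKM. It gave a return share of 85.0% of higher genes and medians of 3.19 for S phase, 5.66 for G2 and M, -2.92 for mural, 0.89 for adipogenic and -2.03 for Wnt and Hedgehog genes. Marker lists gave 3.86 for macrophages, -4.11 for neutrophils, 4.00 for lymphocytes, -2.16 for endothelial cells, 2.95 for satellite cells and -3.34 for Schwann cells. As means, the chemokine list gave 2.39, the tenogenic list 2.05 and the osteogenic list 0.69, and the mean of matrix proteases and inhibitors was near 0 (-0.0043), and the cause was not tested. Without genes spanning under 200 bp the return share of lower genes was 92.9%.

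In the order test, leaving out 1 library at a time gave exact permutation p-values from 0.000794 to 0.154. It was 0.140 without day 1, 0.154 without day 2, 0.0996 without day 3 and 0.0647 without day 7, and the cause was not tested. It was 0.0140 with Euclidean distance, 0.0139 with no filter and 0.0193 with repeated symbols summed. After correction for length and GC content, the 2-fold counts at all 7 days stayed within 1.5 times those reported.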

Other observations

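Of the tests below, those on carried-over myeloid cells, macrophages, the share of sorted cells, dissociation, scaling and imprinted genes, and all added gene lists, were chosen only after the result was seen, and those on length and GC content and on exchanged labels were written before. No biological explanation was tested for the day 5 count, the myeloid transcripts or the immediate early genes, and time since injury stays open for each.

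More genes were 2-fold from quiescent at day 5 than at day 4, at 1.96 times the count. After the trend with transcript length and GC content was removed the ratio was 1.79, which argues against that trend as the whole cause. Genes lower than quiescent were 2.16 times as many at day 5. Added RNA of other cells would dilute all other genes by 1 factor, which median-ratio scaling is meant to remove, and under it the ratio was 2.24, which argues against carried-over myeloid cells as the whole cause. Exchanged labels of the 2 libraries cannot be told apart from the labels as given, since 56.2% of the 1084 genes that differ between days 3 and 7 were closer to day 7 at day 4 than at day 5, between the bounds set beforehand. The G2 and M median, 1.92 at day 4 and 1.58 at day 5, lies in the order of the labels. Against that order, the Spearman correlation of day 3 across genes was higher with day 5 (0.931) than with day 4 (0.912). That of day 7 was also higher with day 5 (0.952) than with day 4 (0.945), which goes with the labels.

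Myeloid transcripts were higher at days 3 and 5 than at day 4. All 16 macrophage markers at 5 FPKM or more at day 3 or 5 (100%) were lower at day 4 than at both, but this restates the pattern, so carried-over macrophages, which the sort for tdTomato is meant to remove, stay open beside uptake of their RNA and expression by the progenitors, neither of them tested. Of the list's 22 genes, 3 stand in another list. Lyz2 (391, 52.6 and 182 FPKM at days 3, 4 and 5) was the most abundant marker named. A lower share of sorted cells would raise all other types. Of the 5 lists of types other than myeloid with at least 3 measured genes, 1 was higher at day 3 than at day 4. That count met the bound set against a lower share. At day 5 all 5 were higher than at day 4, with the lower quartile above 0 in 3 of them, between the bounds. How common each type was in the tissue on each day was not measured. The count therefore cannot decide, also at day 3 where the bound was met, and a lower share stays open at both days. This count replaced one over all 8 lists, and before that an endothelial test. The median of that test, 0.25 for day 5 against day 4, would have argued against a lower share. The high level of Tek, Eng and Aqp1 in these cells would hide a small share of endothelial cells in it.

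The median of the immediate early genes was below quiescent at every injured day, though at day 1 as many of the 22 were 2-fold higher (3) as lower (3), and at day 4 only 1 was 2-fold lower. A scaling factor moves matched random lists of the same library too, and the list's percentile among them was at most 1.09 at the 7 days, which argues against scaling as the cause. This replaced a test under median-ratio scaling that could not have come out otherwise. A response to dissociation in the quiescent library cannot be told apart from a resting level. Every library came from sorted cells, and 1 is quiescent. The heat shock median at day 10, -0.30, lay between the bounds, and 14 of 20 immediate early genes at 10 FPKM or more were highest in quiescent.

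Added lists gave the following. Serine and one-carbon synthesis had a median of 2.17 at day 1 (9 of 12 higher), with Psat1 rising from 2.68 to 80.3. MHC class II had 2.19 at day 3, 0.94 at day 4 and 3.41 at day 5 (6 of 6 measured higher), and macrophage markers were also lower at day 4 than at days 3 and 5 (2.96, 1.23 and 2.65 at days 3, 4 and 5). The metallothionein list, which also holds Slc30a1 and Mtf1, had 0.70 at day 1, within the range of random lists. Of its 5 measured genes 2 were higher, Mt1 (1199.1 to 5047.0) and Mt2 (1940.0 to 9017.7), while Mt3 was lower (1.34 to 0.22). The circadian clock list had -0.74 at day 2 and 0.30 at day 10. At day 10 its members moved both ways, with 4 of 15 higher and 1 lower. Per3 rose from 3.69 to 10.5 there, and the lower gene was Nr1d1 (18.2 to 7.80). Arntl (22.2 to 14.0) stayed within 2-fold.

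Of 24 measured imprinted genes, 11 were at least 2-fold higher than quiescent at day 5 and 9 at day 7. A candidate explanation was a shift of imprinted genes as a set. The full list of 24 measured genes had a median of 0.54 at day 5, at percentile 99.75, but it held the 9 genes whose values had prompted the test (their own median was 1.96), so that result is void. The other 15 had a median of -0.06 at percentile 20.2, but leaving out the high members fixes that outcome too, so the explanation stays open. Muscle fibre markers were higher at the same days (1.18 at day 5 and 1.13 at day 7). At days 3 and 4 their medians were -0.34 and -0.21, inside the range of random lists. Those of the 9 genes were already 1.00 and 0.89. Satellite cell and myoblast genes were higher at these 2 days too (1.18 and 0.38). Carried-over muscle RNA was therefore not separated from a shift of the imprinted genes.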
